A study of Mus musculus with 30 samples.

How the data were processed

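Mouse macrophages sorted on F4/80 and stromal cells sorted on podoplanin (PDPN+) were profiled by RNA sequencing of polyA RNA, in 30 libraries that form 10 groups of 3. The labels place the PDPN+ cells in the omentum, the fatty fold of the abdominal lining. The 18 macrophage libraries comprise cells analysed ex vivo, cells cultured alone, cells cultured with 1 uM all-trans retinoic acid (ATRA), cells from direct co-culture with PDPN+ cells, cells cultured with PDPN+ cells across a transwell membrane, and cells cultured with 1 uM BMS493, an inverse agonist of the retinoic acid receptors. The 12 PDPN+ libraries comprise cells cultured alone, from co-culture, from transwell culture and with BMS493. The labels do not say whether the BMS493 cultures held both cell types, so each BMS493 group was compared both with the co-culture and with the cells alone.

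The deposited tables give, per the file headers, the count of uniquely aligning reads for each of 50764 gene models, and these values were whole numbers. The deposited tables also give, per the file headers, a size-factor-adjusted RPKM made by the authors, which was used only to compare their scaling with the one used here (largest absolute log2 ratio 0.06). The submitters' processing notes name the aligner GSNAP and the genome build GRCm38. The aligner version, the gene annotation, the strand setting and the read filters are not given in the sources used here, so antisense and overlapping genes, and near-identical copies such as Hspa1a and Hspa1b or Lyz2 and its close relative Lyz1, cannot be separated with certainty. Of the gene identifiers, 192 have no symbol and hold 0.0358% of the counts. Gene coordinates come from the GENCODE annotation of GRCm38 and count from 1.

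Total counts ranged from 29350158 to 54099085 per library, and 22152 to 26345 genes had at least 1 count. The libraries were made from 2148 to 25000 sorted cells with RNA integrity numbers of 9.2 to 10. The fewest cells lay behind PDPN+ co-culture replicates 2 and 3 (3730 and 2148 cells). No pair of replicates was a copy of another, since the lowest chi-square per degree of freedom between replicates was 49.02. Where a group held no count of a gene, the fold is given as a lower bound against a floor of 3 counts over the group. With 1 to 3 counts it is given as a ratio with its exact 95% binomial interval. Floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

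Genes were tested with the edgeR 4.0.16 quasi-likelihood test (R 4.3.3, limma 3.58.1) after TMM scaling and edgeR's default low count filter by group. Each cell type had its own fit, over 17774 genes in 18 macrophage libraries and 19134 genes in 12 PDPN+ libraries, with group as the only factor. The common biological coefficient of variation was 0.499 in macrophages and 0.573 in PDPN+ cells. The Benjamini-Hochberg method adjusted p over all genes tested in a comparison, and a gene was called at an adjusted p under 0.05. Every adjusted p quoted for a gene is from this test unless another is named. The standard error of a log2 fold change is its size divided by the square root of the F statistic. Levels are CPM, counts relative to the TMM-scaled library total over all 30 libraries, given as mean ± SD of 3 libraries. Log2 fold changes are the fitted values of edgeR. Nothing in the labels says whether the replicates come from separate animals or separate cultures, so the p values measure only the spread between these samples.

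The labels give 3 processing batches (336, 339 and 340), each holding the replicate of the same number from every group. The numbers therefore pair the libraries by label. Deviations from the group means correlated between same-numbered macrophage libraries with a median r of 0.186 across genes (range -0.0883 to 0.635, 28 of 45 pairs over 0.1), against a median of -0.0864 between other libraries. In PDPN+ cells the median was 0.11 (range -0.272 to 0.54, 10 of 18 pairs over 0.1), against -0.0748. Deviations cancel out within a group, so the values between other libraries largely follow from the same-numbered ones and are no separate evidence. A fit with batch as a block was therefore run beside each comparison. In batch 336 the source names of the co-culture pair carry each other's cell type, in conflict with the titles and group labels. The titles were used, and Adgre1, the F4/80 gene, lay at 2699 CPM or more in the macrophage co-culture libraries and at 62.5 CPM or less in the PDPN+ ones.

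The comparisons, the gene lists, the naming rule and most alternative settings were fixed before the data were examined. In all, 14 comparisons were made, 9 in macrophages and 5 in PDPN+ cells. The genes named are the called genes with the largest change in each direction (up to 8, or 4 in secondary comparisons) with a mean of at least 10 CPM in the higher group, no overlap between the replicates of the groups and a proper gene symbol. In comparisons of cells that had met the other cell type, genes at more than 4 times the level in the other cell type cultured alone were set apart as possible carry-over, with up to 3 named. Up to 4 members of a list are named by smallest adjusted p, and 8 genes per cell type are always given. F5, Prg4, Alox15, Upk3b, Upk1b, Lrrn4, Gpm6a, Gm42503, and the genes named for batch 340 were added after their values were seen. Some genes that the rule names are not reported here.

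The 24 gene lists hold 319 genes, all found in the tables: cavity macrophage programme, retinoic acid response, retinoid uptake and synthesis, pan-macrophage, fibroblast, mesothelial, B cell, T cell, mast cell, granulocyte, endothelial, MHC class II, alternative activation, cell cycle, inflammatory cytokine, type I interferon response, cholesterol synthesis, LXR targets, immediate early, extracellular matrix and contractile, stromal cytokine and chemokine, unfolded protein and amino acid stress, heat shock, and hypoxia and glycolysis. They were written from general knowledge. Lists were tested against all other genes with camera (limma) at its preset correlation of 0.01, adjusted over the 24 lists of a comparison. Camera with an estimated correlation, fry and the blocked fit were the alternatives. Of 112 list calls over the 14 comparisons, 28 held with an estimated correlation.

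Alternative settings for the genes were RLE scaling, no low count filter, a filter at a mean of 5 CPM, DESeq2 1.42.0, a fit of the 6 compared libraries alone, a fold threshold of 1 on the log2 scale, the batch block, removal of carry-over genes, removal of libraries from under 10000 cells, and removal of each library in turn. Leaving out batch 340, leaving out a pair of PDPN+ libraries, and a joint fit of both cell types were added after the data were seen. RLE scaling moved the median log2 fold change of all genes by at most 0.0365 in any comparison. The edgeR test was also tried on simulated counts (16649 genes) drawn from the mean of macrophages alone and the fitted dispersions. Changes were given to the co-culture libraries, only at genes of 5 CPM or more in the cells alone. It recovered 14 of 100 genes changed by 1 on the log2 scale and 77 of 100 changed by 2, with 3 false calls. For the same comparison in PDPN+ cells (17860 genes), drawn from the cells alone, it recovered 0 of 100 and 25 of 100, with 1 false call. The simulation held no batch differences, so recovery and false calls in the real data may differ. Figures were drawn with matplotlib 3.10.9.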

Results

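The series measured polyA RNA in mouse macrophages and PDPN+ stromal cells, in 30 libraries of 10 groups with 3 libraries each, at 29350158 to 54099085 counts per library. Its title links macrophages with vitamin A, whose active metabolite is retinoic acid. The design asks how macrophages change in culture, how they respond to ATRA or to PDPN+ cells in contact or across a membrane, and what the receptor inverse agonist BMS493 does to both cell types. Adgre1, which encodes F4/80, lay between 1789 and 4851 CPM in the macrophage libraries and between 0.708 and 1.23 CPM in PDPN+ cells cultured alone. Col1a1, a collagen chain of fibroblasts, averaged 3261 ± 2363 CPM in PDPN+ cells cultured alone and 4.18 ± 3.29 CPM in macrophages cultured alone (n = 3 each). Pdpn itself averaged 175 ± 19.4 CPM in PDPN+ cells cultured alone, but it also ranged from 0.312 to 223 CPM in the macrophages cultured alone, with the highest value in batch 340. It reached 329 CPM in co-culture macrophages and 683 CPM in BMS493 macrophages, against at most 215 CPM in any PDPN+ library.

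Transcripts of the partner cell were present after direct co-culture. The fibroblast list in co-culture macrophages exceeded its level in macrophages alone by 2.13% of the level in co-culture PDPN+ cells (median of 16 genes, 3.19%, 1.58% and 0.916% in replicates 1, 2 and 3). The value was 0.036% after transwell culture and 3.0% in the BMS493 group. Pan-macrophage genes in PDPN+ cells rose over the cells alone by 1.37% of the macrophage level after co-culture (1.45%, 1.2% and 1.51% in replicates 1, 2 and 3), by 0.209% after transwell culture (0.393%, 0.0223% and 0.0118%) and by 1.74% with BMS493 (1.03%, 2.03% and 2.14%). In both BMS493 groups these values lay near those of direct co-culture and above those of transwell culture. This argues that the BMS493 cultures held both cell types, although the labels do not say so. Comparisons of BMS493 groups with cells cultured without the partner therefore cannot separate BMS493 from the partner cells. Batch 340 also stood apart in the cultured macrophages: its 5 libraries differed from the 10 others at 4698 of 17218 genes with group in the fit.

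**Figure D1:**
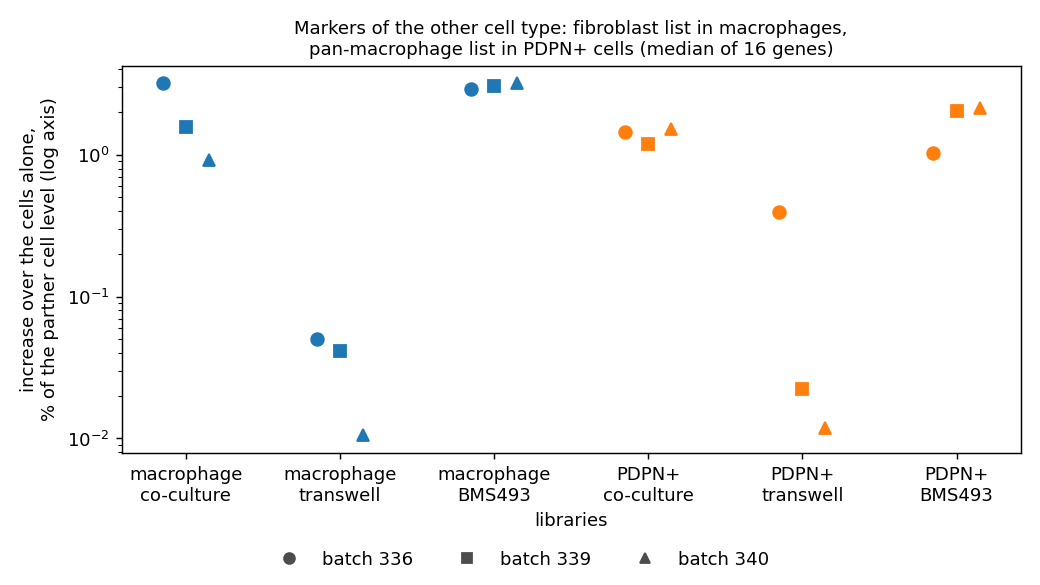
Increase of partner cell markers over the cells cultured alone, as % of the level in the partner cell (log axis), with a point per replicate and the shape giving the batch. The medians of the list were 2.13% in co-culture macrophages and 3.0% in BMS493 macrophages, against 0.036% in transwell macrophages.

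Macrophages cultured alone lost much of the transcript programme of cavity macrophages when set against macrophages analysed ex vivo. Gata6, the transcription factor of resident peritoneal macrophages (chromosome 18, 11052064 to 11085635), fell 12.4-fold from 69.0 ± 45.6 to 5.47 ± 1.89 CPM (log2 fold change -3.64, SE 0.535, adjusted p = 0.000305, edgeR, n = 3). Selp, which encodes P-selectin (chromosome 1, 164115264 to 164150026), fell 83.6-fold to 12.5 ± 2.77 CPM. Rarb, a retinoic acid receptor that retinoic acid itself induces (chromosome 14, 16430839 to 16819156), fell 41.6-fold to 1.58 ± 1.08 CPM (adjusted p = 7.72e-06). Cyp26a1, an enzyme that degrades retinoic acid (chromosome 19, 37697798 to 37701536), went from 28.5 ± 9.56 CPM to 0 counts, which is at least 994-fold lower.

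Of the 26 measured members of the cavity macrophage programme, 16 fell and 0 rose after culture alone, or 17 and 1 when adjusted over the list alone. They included the adhesion molecule gene Icam2 (49.7-fold), Garnl3 (36.1-fold), the coagulation factor gene F5 (66.2-fold), Prg4 (142-fold) and the lipoxygenase gene Alox15 (48.7-fold). Timd4, a receptor for phosphatidylserine, fell 26.8-fold (adjusted p = 0.0385) and Tgfb2 fell 9.50-fold (adjusted p = 0.0259). The list as a whole fell (camera adjusted p = 2.61e-17, and adjusted p = 0.00747 with an estimated correlation). In the retinoic acid response list 6 of 16 members fell and 1 rose, the same counts as when adjusted over the list alone, and the list fell (camera adjusted p = 0.00262, adjusted p = 0.0336 with an estimated correlation). Among them the receptor gene Rarg fell 5.66-fold and the corepressor gene Nrip1 fell 3.43-fold, while Tgm2, a transglutaminase gene, rose 8.72-fold from 17.3 ± 10.7 to 150 ± 45.5 CPM. Cyp26b1 fell from 3.12 ± 1.45 CPM to 6 counts, all in alone replicate 1 (adjusted p = 0.0321), and kept this call in 1 of 6 omissions of a library (adjusted p = 0.0977 without alone replicate 2). Aldh1a2, which encodes an enzyme that makes retinoic acid, fell 18.5-fold, and Rdh11 rose 1.89-fold. Their list of 7 retinoid uptake and synthesis genes did not pass (camera adjusted p = 0.548). Adgre1 (log2 fold change -0.66, SE 0.259, adjusted p = 0.0915) and Arg1 (0.88, SE 1.25, adjusted p = 0.698) were not called. The direction for Arg1 is not settled, since its log2 fold change was -0.61 in the blocked fit, below 0 without alone replicate 3 (adjusted p = 0.0854) and -3.233 without batch 340 (adjusted p = 0.019).

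The largest decreases beside Cyp26a1 were those of Retnla, a secreted marker of alternative activation (1591-fold, from 595 ± 80.6 CPM), Pglyrp1, a peptidoglycan receptor gene (ratio 1670, counting interval 300 to 66000, against 1 count), and Hgd, a tyrosine catabolism gene (ratio 760, interval 210 to 6280, against 2 counts). Sorcs2 fell 333-fold, the histidine decarboxylase gene Hdc 326-fold, the hyaluronan receptor gene Lyve1 274-fold and the interferon-induced GTPase gene Gbp2b 254-fold. Among the largest increases, Spint1, a protease inhibitor gene, was at least 2680-fold higher at 80.3 ± 106 CPM (at least 887-fold without alone replicate 3) and Ms4a14 at least 669-fold higher (437-fold without alone replicate 1), each against 0 counts ex vivo. The metalloproteinase genes Mmp8 (1059 ± 1570 CPM), Mmp12 (4207 ± 6045 CPM) and Mmp13 (283 ± 455 CPM) and the cystine transporter gene Slc7a11 (335 ± 500 CPM) rose with a spread larger than their mean, all from under 1 CPM, and Mmp13 had an adjusted p = 0.055 without ex vivo replicate 2. Gsta3, a glutathione transferase gene, rose 2437-fold to 141 ± 37.8 CPM and Ms4a7 rose 1838-fold to 736 ± 315 CPM.

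Genes of cholesterol synthesis rose together after culture alone: 15 of 17 rose (17 adjusted over the list alone), with Cyp51 up 9.96-fold, Msmo1 8.46-fold, Fdft1 5.89-fold and Hmgcs1 5.30-fold (camera adjusted p = 3.34e-21, adjusted p = 0.0324 with an estimated correlation). Cell cycle genes fell in 21 of 23 cases (23 adjusted over the list alone), among them the replication licensing genes Mcm7 (10.2-fold), Mcm6 (8.75-fold), Mcm4 (5.76-fold) and Mcm3 (4.02-fold). That list's camera adjusted p was 3.03e-15, with an adjusted p = 0.301 with an estimated correlation. In the heat shock list 4 of 9 members fell, led by the near-identical copies Hspa1b (72.7-fold) and Hspa1a (30.9-fold), and 0 rose, also when adjusted over the list alone (camera adjusted p = 9.12e-05, adjusted p = 0.0892 with an estimated correlation). In the hypoxia and glycolysis list 6 of 17 rose and 1 fell (7 and 1 adjusted over the list alone), with the growth factor gene Vegfa up 143-fold and Aldoa 2.90-fold (camera adjusted p = 0.0262, adjusted p = 0.659 with an estimated correlation). In the inflammatory cytokine list 5 of 18 rose (8 adjusted over the list alone), including Icam1 (4.60-fold), Tnf (15.8-fold) and Ccl3 (43.8-fold), with camera adjusted p = 0.0133 and adjusted p = 0.659 with an estimated correlation. Of the 18 members, 14 were higher in the cultured macrophages of batch 340 than in those of the other batches, with group in the fit. Without alone replicate 3, of batch 340, Ccl2 (adjusted p = 0.699) and Ccl7 (0.428) were not called, while Icam1, Tnf and Ccl3 kept their calls whichever of the 6 libraries was left out. The extracellular matrix and contractile list had 2 of 16 members higher and 1 lower (6 and 1 adjusted over the list alone), and its camera adjusted p of 0.0262 became 0.0793 in the blocked fit and an adjusted p = 0.623 with an estimated correlation.

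The other lists did not pass as groups, with camera adjusted p from 0.0582 (MHC class II) to 0.885. MHC class II had 3 of 7 members lower (H2-Aa 8.38-fold, H2-Eb1 6.99-fold and Cd74 4.73-fold). Alternative activation had 2 of 12 higher (Mrc1 12.7-fold) and 3 lower (4 and 5 adjusted over the list alone). Pan-macrophage genes had 3 of 16 higher (Ctss 3.06-fold, Fcer1g 2.46-fold, Cd68 2.19-fold) and 2 lower (Laptm5 and Itgam). Unfolded protein and amino acid stress had 2 of 13 higher and 5 lower (3 and 6 adjusted over the list alone), with the chaperone gene Hspa5 down 3.07-fold. Immediate early genes had 4 of 16 higher and 4 lower (7 and 5 adjusted over the list alone), with Egr2 up 42.0-fold and Klf2 down 24.3-fold. The type I interferon response had 2 of 15 higher and 1 lower, and LXR targets 1 of 8 lower (Abcg1, 3.42-fold). The stromal cytokine and chemokine list had 3 of 13 higher (Icam1, Ccl2 and Ccl7, the last at 0.0621 in the blocked fit), all of which also stand in the inflammatory cytokine list, and Ccl2 and Ccl7 rest on alone replicate 3 as given there. Among markers of other cells, 1 of 7 B cell genes (Cd22, 40.1-fold), 1 of 7 T cell genes (Il7r, 154-fold), 1 of 3 granulocyte genes (S100a8, 11.3-fold) and 1 of 4 endothelial genes (Vwf, 36.5-fold, adjusted p = 0.121 without ex vivo replicate 2) rose, and 0 of 6 mast cell, 0 of 15 fibroblast and 0 of 8 mesothelial genes were called in edgeR. Adjusted over the list alone the endothelial count was 2 and the counts of the remaining lists were the same. Over all genes 3164 of 17774 were called, 1654 higher and 1510 lower. Without ex vivo replicate 2 the count was 2107, and a fit of these 6 libraries alone called 1952.

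ATRA at 1 uM raised retinoic acid response genes and part of the cavity programme over macrophages cultured alone. Cyp26a1 rose from 0 counts to 224 ± 148 CPM, at least 7240-fold. Gata6 rose 13.7-fold to 77.0 ± 27.6 CPM (log2 fold change 3.77, SE 0.538, adjusted p = 0.00509, edgeR, n = 3) and Rarb rose 14.9-fold to 23.8 ± 9.96 CPM (adjusted p = 0.00206). Selp rose 32.5-fold to 415 ± 180 CPM (adjusted p = 0.000131), F5 24.5-fold and P2rx1, an ATP-gated channel gene, 38.9-fold. Nrip1 rose 6.68-fold and Aldh1a2 22.6-fold to 31.6 ± 10.1 CPM.

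Other large increases with ATRA were those of the kinase gene Camkk1 (to 41.4 ± 12.2 CPM from 0.301 ± 0.521 CPM, held by alone replicate 1 only, adjusted p = 0.0201, and 0.0823 without alone replicate 2), the casein gene Csn3 (37.5-fold), the protease inhibitor gene Cst7 (24.9-fold) and the basement membrane collagen gene Col4a1 (22.7-fold). The 8 genes that fell included the immune checkpoint gene Havcr2 (7.03-fold), the adhesion gene Cadm1 (6.26-fold, to 7.66 ± 2.82 CPM), the sulfatase gene Sulf2 (3.16-fold), Cbr3 (2.78-fold), Ms4a6d (2.64-fold) and the sphingosine 1-phosphate receptor gene S1pr2 (1.89-fold). Icam2 (log2 fold change 1.66, SE 0.493, adjusted p = 0.255), Timd4 (2.12, SE 1.33, adjusted p = 0.821), Arg1 (2.18, SE 1.29, adjusted p = 0.794), Tgfb2 (-0.15, SE 0.868) and Adgre1 (0.37, SE 0.258) were not called.

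In the cavity macrophage programme 4 of 26 members rose with ATRA (13 adjusted over the list alone), and in the retinoic acid response list 3 of 16 (6 adjusted over the list alone). Both lists rose (camera adjusted p = 1.53e-26 and 4.06e-15, and adjusted p = 0.000521 and 5.12e-05 with an estimated correlation). The calls of 5 further lists were lost with an estimated correlation. They were hypoxia and glycolysis with 1 of 17 higher (Hk2, 2.35-fold, 5 adjusted over the list alone, adjusted p = 0.356 with an estimated correlation), extracellular matrix and contractile with 1 of 16 higher (3 higher and 1 lower adjusted over the list alone, adjusted p = 0.425), retinoid uptake and synthesis with Aldh1a2 alone (adjusted p = 0.106), alternative activation with 0 of 12 (3 adjusted over the list alone, adjusted p = 0.13) and mast cell with 0 of 6 (adjusted p = 0.669). The fibroblast list, at camera adjusted p = 0.0556, reached 0.0421 in the blocked fit. In cholesterol synthesis Sc5d alone rose, 3.18-fold (adjusted p = 0.00206). In all 58 genes were called, 50 higher and 8 lower, against 143 in the blocked fit, 331 with DESeq2, 106 without batch 340 and 3 in a fit of these 6 libraries alone. Leaving out alone replicate 2 left 17 calls and leaving out ATRA replicate 2 left 22. Gata6, Rarb, Selp and Cyp26a1 kept their calls whichever of the 6 libraries was left out. Over the other alternative settings, the highest adjusted p was 0.0808 for Gata6, 0.188 for Rarb and 0.0808 for Cyp26a1, so these calls were not kept throughout. For Selp it was 0.047.

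**Figure D2:**
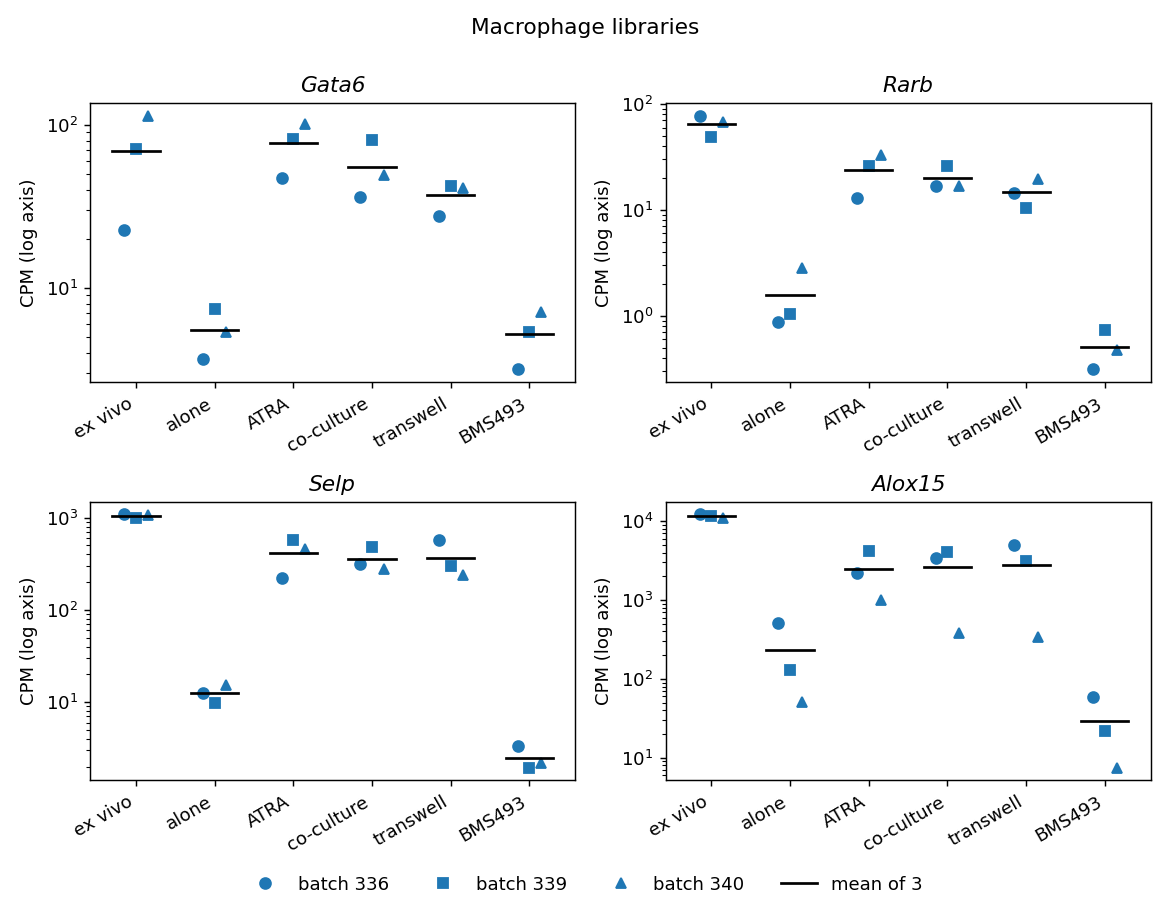
Levels of Gata6, Rarb, Selp and Alox15 in CPM (log axis) in the 6 macrophage groups, with a point per library, the shape giving the batch and the bar the mean of 3. Mean Gata6 was 69.0 CPM ex vivo, 5.47 alone, 77.0 with ATRA, 55.3 in co-culture, 37.0 in transwell culture and 5.20 with BMS493.

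Macrophages from co-culture with PDPN+ cells also had more of these transcripts than macrophages alone. Selp was 27.6-fold higher at 357 ± 112 CPM (log2 fold change 4.79, SE 0.429, adjusted p = 0.000216, edgeR, n = 3), Rarb 12.4-fold higher at 19.9 ± 5.22 CPM (adjusted p = 0.00439) and Gata6 9.71-fold higher at 55.3 ± 23.1 CPM (adjusted p = 0.0127). Cyp26a1 was at least 357-fold higher at 11.2 ± 7.10 CPM. F5 rose 13.7-fold, P2rx1 13.0-fold and Nrip1 2.96-fold. Aldh1a2 rose 10.7-fold to 15.1 ± 2.49 CPM, and its level in the co-culture PDPN+ cells was 303 ± 118 CPM.

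The possible carry-over class holds genes over 4 times higher in PDPN+ cells alone than in macrophages alone. Gata6 (154.9 CPM in PDPN+ cells alone against 5.47 CPM in macrophages alone), Rarb, Cyp26a1 and Aldh1a2 are of that class. The count without carry-over genes given below therefore leaves them out. Outside the class, large increases beside Selp, F5 and P2rx1 were those of the adhesion gene Pecam1 (15.3-fold), the interferon-induced transmembrane gene Ifitm6 (15.3-fold), the acyltransferase gene Gpat3 (12.6-fold), Cass4 (11.8-fold) and Tspan18 (11.1-fold). The 12 genes that fell included Cadm1 (9.04-fold), the adhesion receptor gene Adgre4 (4.76-fold), Sulf2 (4.59-fold), the glutathione transferase gene Gstm1 (3.46-fold), Cib2 (3.24-fold), Glipr1 (2.31-fold), Tmem50b (2.12-fold) and the nucleoside transporter gene Slc29a1 (2.11-fold). Icam2 reached 93.1 ± 30.6 CPM with an adjusted p = 0.0595, and 0.0155 in the blocked fit. Arg1 averaged 13550 ± 3061 CPM against 1483 ± 2406 CPM alone and was not called (adjusted p = 0.333), nor were Timd4 (adjusted p = 0.785), Tgfb2 (adjusted p = 0.779) and Adgre1 (adjusted p = 0.736).

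Matrix and contractile genes of stromal cells were among those that rose. In the extracellular matrix and contractile list 7 of 16 rose and in the fibroblast list 3 of 15 (11 higher in each adjusted over the list alone, with 1 lower in the former). Examples are the smooth muscle actin gene Acta2 (20.5-fold, to 141 ± 77.9 CPM), Myl9 (73.0-fold), Tagln (19.1-fold), Sparc (41.4-fold) and Col1a1 (38.6-fold, to 167 ± 115 CPM). The lists rose with camera adjusted p = 3.47e-22 and 1.49e-14, and adjusted p = 0.00233 and 0.0219 with an estimated correlation. Of the 112 genes higher in co-culture macrophages, 62 lay over 4 times higher in PDPN+ cells alone than in macrophages alone, including Col5a2 (197-fold) and Ackr3 (104-fold). Their increase was a median 2.81% of the level in co-culture PDPN+ cells, beside 2.13% for the fibroblast list.

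In the cavity macrophage programme 4 of 26 rose in co-culture (11 adjusted over the list alone) and in the retinoic acid response list 3 of 16 (8 adjusted over the list alone), with camera adjusted p = 4.02e-17 and 8.15e-09, and adjusted p = 0.00317 and 0.000943 with an estimated correlation. Hypoxia and glycolysis rose as a list (camera adjusted p = 6.65e-19, adjusted p = 0.0219 with an estimated correlation), with Hk2 (2.44-fold) and P4ha1 (2.01-fold) called, and 16 of 17 higher when adjusted over the list alone. Retinoid uptake and synthesis (1 of 7 higher, Aldh1a2) and the endothelial list (1 of 4 higher, Pecam1) also held, with adjusted p = 0.0259 and 0.0476 with an estimated correlation. Aldh1a2 is of the possible carry-over class, so PDPN+ RNA may supply part of the former rise. With an estimated correlation the calls of 7 lists were lost: cell cycle (adjusted p = 0.361), mesothelial (0.479), immediate early (0.274), stromal cytokine and chemokine (0.206), heat shock (0.206), unfolded protein and amino acid stress (0.135), all higher, and T cell (0.189), lower. The inflammatory cytokine list passed only in the blocked fit (camera adjusted p = 0.0222). In all 124 genes were called, 112 higher and 12 lower, against 429 in the blocked fit, 703 with DESeq2, 48 without carry-over genes (62 of the 124 are of that class, and p was adjusted again over the genes left), 930 without batch 340 and 1 in a fit of these 6 libraries alone. The count was 5 without alone replicate 2, where Gata6 (adjusted p = 0.0679), Rarb (adjusted p = 0.058) and Cyp26a1 (adjusted p = 0.124) were no longer called and Selp was (adjusted p = 0.00703), 28 without co-culture replicate 2, 56 without alone replicate 1 or co-culture replicate 1, and 268 without alone replicate 3.

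**Figure D3:**
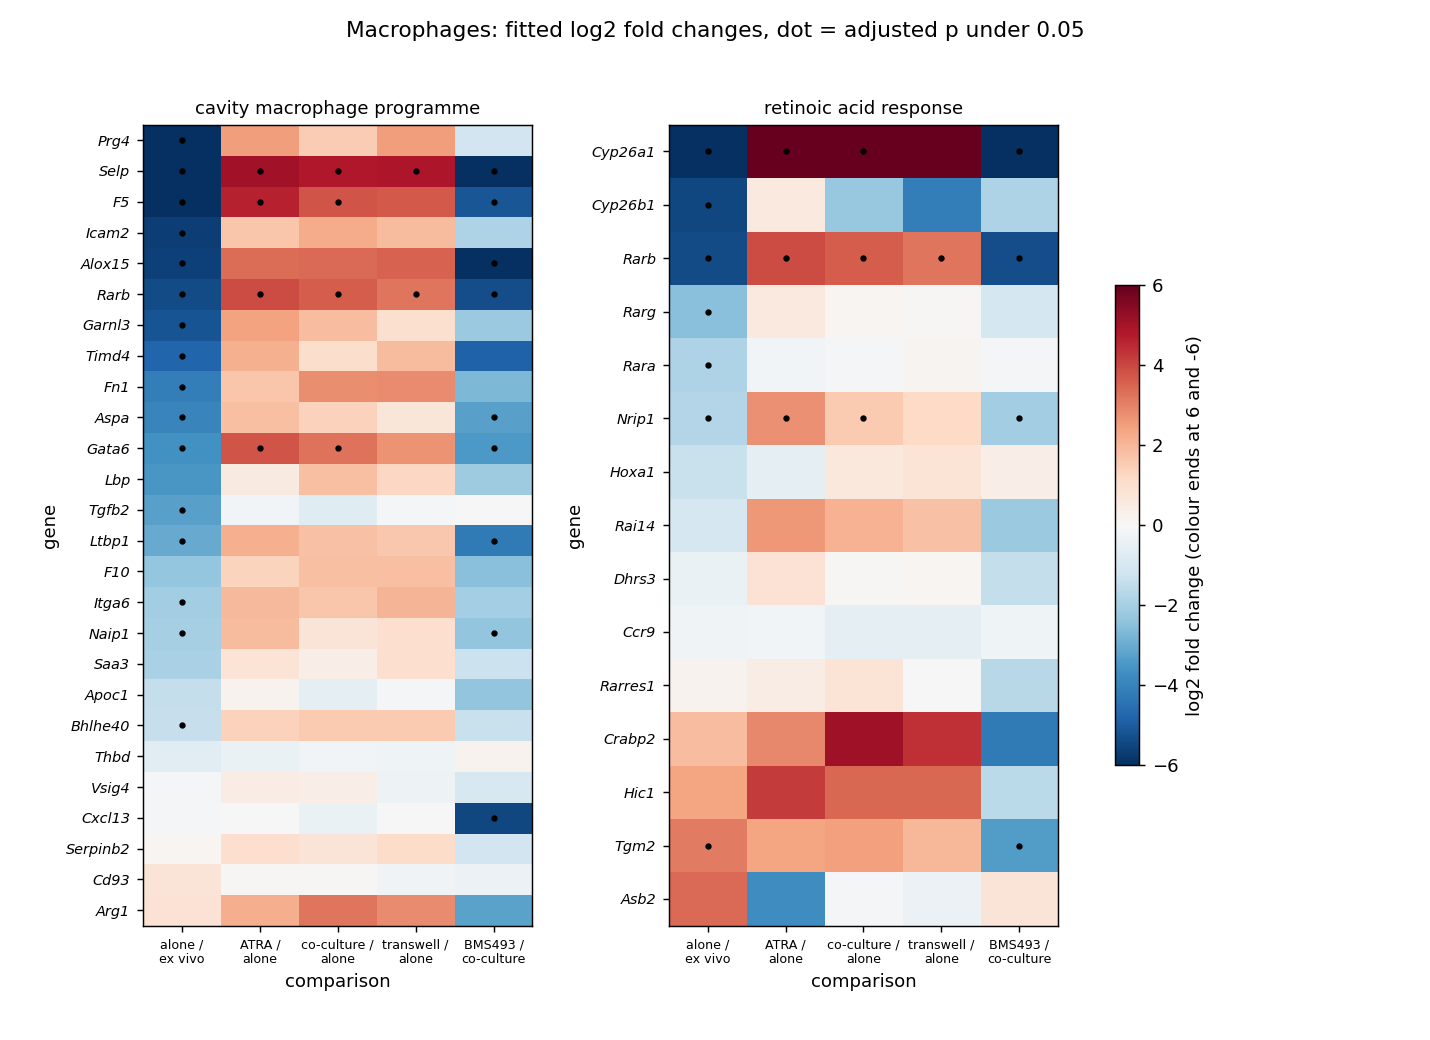
Fitted log2 fold changes of members of the cavity macrophage programme and the retinoic acid response list in 5 macrophage comparisons (colour, red higher and blue lower), with a dot at an adjusted p under 0.05. In the cavity list 16 members fell after culture alone, 4 rose with ATRA, 4 rose in co-culture, 2 rose in transwell culture and 9 fell with BMS493.

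Across a transwell membrane, where the fibroblast list rose by only 0.036% of its PDPN+ level, 5 genes were higher than in macrophages alone and 0 were lower. Selp rose 28.9-fold to 369 ± 176 CPM (log2 fold change 4.85, SE 0.430, adjusted p = 0.000186, edgeR, n = 3). Rarb rose 9.33-fold to 14.9 ± 4.69 CPM (adjusted p = 0.0373), Cass4 11.5-fold, the mitochondrial calcium channel gene Mcu 2.95-fold and the interferon-induced gene Ifitm3 2.84-fold. Gata6 averaged 37.0 ± 8.18 CPM, 6.54 times its level alone, with an adjusted p = 0.107, and 0.00591 in the blocked fit. Icam2 (adjusted p = 0.252), Arg1 (0.519), Timd4 (0.695), Tgfb2 (0.985) and Adgre1 (0.855) were not called.

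In transwell macrophages the cavity macrophage programme rose as a list (2 of 26 members called, 12 adjusted over the list alone, camera adjusted p = 1.28e-19), as did the retinoic acid response list (1 of 16, 4 adjusted over the list alone, camera adjusted p = 2.65e-06). Each held at an adjusted p = 0.00239 with an estimated correlation. The calls of 5 lists were lost with an estimated correlation: hypoxia and glycolysis (adjusted p = 0.104, 7 of 17 higher adjusted over the list alone), cell cycle (0.664), immediate early (0.296), unfolded protein and amino acid stress (0.443) and mast cell (0.443), each with 0 members called in edgeR. The inflammatory cytokine list passed only in the blocked fit (camera adjusted p = 0.0161). The blocked fit called 23 genes, all higher, and DESeq2 called 262, against 323 without batch 340, 3 with RLE scaling and 0 in a fit of these 6 libraries alone. The count of 5 fell to 1 without alone replicate 2, transwell replicate 1 or transwell replicate 3, and to 2 without alone replicate 1 or transwell replicate 2, and was 43 without alone replicate 3. Selp was called each time, whereas Rarb had an adjusted p = 0.222 without alone replicate 2.

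Direct contact against transwell culture changed 7 genes in macrophages, all higher and all of the possible carry-over class. They included the muscle filament gene Des (52.9-fold, to 29.4 ± 21.8 CPM), Myl9 (48.5-fold) and Acta2 (26.7-fold, adjusted p = 0.00461, edgeR, n = 3). Gata6 (log2 fold change 0.57, SE 0.482), Rarb (0.41, SE 0.415), Icam2 (0.32, SE 0.480) and Arg1 (0.35, SE 1.24) were not called, each at an adjusted p of 1, and Timd4, Tgfb2 and Adgre1 were not called either. The extracellular matrix and contractile list rose (3 of 16, 10 adjusted over the list alone, adjusted p = 0.000457 with an estimated correlation), as did the fibroblast list (0 of 15, 11 adjusted over the list alone, adjusted p = 0.00959 with an estimated correlation). The retinoic acid response list had 0 of 16 called, with camera adjusted p = 0.0199 and adjusted p = 0.0958 with an estimated correlation. Camera also called 7 lists with 0 members called whose calls were lost with an estimated correlation: retinoid uptake and synthesis (adjusted p = 0.0958), endothelial (0.148), mesothelial (0.465), stromal cytokine and chemokine (0.242) and hypoxia and glycolysis (0.474), all higher, and T cell (0.148) and mast cell (0.465), lower. The unfolded protein list passed only in the blocked fit (camera adjusted p = 0.0333), and in the heat shock list Hspb1 alone rose, 25.3-fold. The blocked fit called 33 genes and DESeq2 152, and removal of carry-over genes left 0 in edgeR. Without transwell replicate 2 or 3 the count was 0, without replicate 1 of either group it was 1, without co-culture replicate 2 it was 4 and without co-culture replicate 3 it was 14.

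With 1 uM BMS493, macrophages had less of the same transcripts than macrophages from co-culture. Selp fell 144-fold from 357 ± 112 CPM (log2 fold change -7.18, SE 0.482, adjusted p = 4.06e-06, edgeR, n = 3), Rarb fell 39.5-fold to 0.512 ± 0.216 CPM (adjusted p = 0.000208) and Gata6 fell 10.8-fold to 5.20 ± 1.97 CPM (adjusted p = 0.00569). Alox15 fell 89.8-fold from 2603 ± 1952 CPM (adjusted p = 0.177 without BMS493 replicate 2), P2rx1 93.9-fold and the chemokine gene Ccl24 225-fold (adjusted p = 0.105 without BMS493 replicate 2). The fibroblast list stood at 3.0% of the PDPN+ level in these libraries and at 2.13% in the co-culture libraries.

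Further decreases with BMS493 were those of the serine protease gene Prtn3 (263-fold), Ubash3a (174-fold, adjusted p = 0.199 without BMS493 replicate 2), the tryptophan dioxygenase gene Tdo2 (116-fold) and the growth factor gene Bmp2 (44.9-fold), and in the possible carry-over class Cyp26a1 (150-fold), Camkk1 (90.4-fold, adjusted p = 0.114 without BMS493 replicate 1) and Ackr3 (74.6-fold). Without BMS493 replicate 2 the adjusted p was 0.152 for Prtn3, 0.185 for Cyp26a1 and 0.188 for Ackr3. Without BMS493 replicate 1 it was 0.167 for Tdo2 and 0.0941 for Bmp2. The 22 genes that rose included Cadm1 (15.1-fold, to 83.4 ± 43.3 CPM), Slamf7 (4.69-fold), Sulf2 (4.46-fold), Havcr2 (4.26-fold), Prr5l (4.15-fold), the sterol exporter gene Abcg1 (3.56-fold), Tns3 (3.28-fold) and Eid1 (2.98-fold). Icam2 had an adjusted p = 0.115 and Timd4 an adjusted p = 0.234, which were 0.0456 and 0.0268 in the blocked fit. Arg1 (adjusted p = 0.476), Tgfb2 (1) and Adgre1 (0.454) were not called.

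Against co-culture, 9 of 26 members of the cavity macrophage programme fell with BMS493 (16 adjusted over the list alone), including Ltbp1 (18.7-fold), F5 (35.3-fold) and Naip1 (5.08-fold), and 4 of 16 in the retinoic acid response list (7 adjusted over the list alone), including Nrip1 (4.29-fold) and Tgm2 (10.1-fold). The lists fell with camera adjusted p = 4.15e-42 and 2e-15, and adjusted p = 8.69e-05 and 3.17e-05 with an estimated correlation. Alternative activation fell too (1 of 12, 2 adjusted over the list alone, adjusted p = 0.0497 with an estimated correlation). Hypoxia and glycolysis had 2 of 17 lower (Vegfa 7.90-fold, Hk2 2.30-fold, 5 adjusted over the list alone) with camera adjusted p = 2e-06 and adjusted p = 0.308 with an estimated correlation. The type I interferon and extracellular matrix lists, higher, and the endothelial list, lower (Pecam1 21.3-fold), each at camera adjusted p = 0.0471, were not called in the blocked fit (0.0508, 0.0633 and 0.0843). The mast cell list was lower at 0.0471 too, and with an estimated correlation these 4 lists had adjusted p of 0.685, 0.685, 0.183 and 0.685. The immediate early list passed only in the blocked fit (camera adjusted p = 0.0213). In all 22 genes were higher and 129 lower, against 320 in the blocked fit, 444 with DESeq2, 314 without batch 340 and 75 in a fit of these 6 libraries alone. The count was 43 without BMS493 replicate 2, where Gata6 had an adjusted p = 0.0515, 48 without BMS493 replicate 1, 50 without co-culture replicate 2 and 99 without co-culture replicate 1.

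Against macrophages cultured alone, the BMS493 group had Selp 5.24-fold lower (adjusted p = 0.0119, edgeR, n = 3), the chemokine gene Cxcl13 57.5-fold lower at 11.3 ± 5.31 CPM, Adgre4 42.7-fold lower, Bmp2 39.3-fold lower and Tbc1d8 6.10-fold lower. This comparison cannot separate BMS493 from a presence of PDPN+ cells in the culture. Havcr2 (7.55-fold), the hyaluronidase gene Hyal1 (3.24-fold), the transcription factor gene Etv1 (2.91-fold) and Tbc1d8b (2.59-fold) were higher. Gata6 was within 1.11-fold (log2 fold change -0.16, SE 0.491, adjusted p = 0.913) and Rarb was not called (log2 fold change -1.68, SE 0.471, adjusted p = 0.122), nor were Timd4, Icam2, Tgfb2, Arg1 and Adgre1. Stromal genes rose as in co-culture, with 7 of 16 extracellular matrix and contractile genes (14 adjusted over the list alone), among them Cnn1 and Ccn1, and 5 of 15 fibroblast genes (12 adjusted over the list alone), and adjusted p = 0.00256 and 0.0152 with an estimated correlation. Examples are Col5a2 (254-fold), Sod3 (126-fold) and Pdgfrb, which was at least 233-fold higher. Retinoid uptake and synthesis rose with Aldh1a2 (9.54-fold) called and adjusted p = 0.0149 with an estimated correlation. Aldh1a2 is of the possible carry-over class, so PDPN+ RNA may supply part of this rise. The cavity list fell (2 of 26, 6 adjusted over the list alone, camera adjusted p = 4.36e-05) with an adjusted p = 0.144 with an estimated correlation. The cell cycle list (0 of 23 called, adjusted p = 0.331 with an estimated correlation) and the interferon list (0 of 15, adjusted p = 0.345) were higher by camera only, as were hypoxia and glycolysis (0 of 17, adjusted p = 0.331), heat shock (Hspb1 alone, adjusted p = 0.287), stromal cytokine and chemokine (0 of 13, adjusted p = 0.287) and mesothelial (0 of 8, adjusted p = 0.383). The T cell list, lower, and the unfolded protein list, higher, passed only in the blocked fit (camera adjusted p = 0.0255 and 0.0318). Of 131 called genes 98 were higher and 33 lower, and 90 of the 131 are of the possible carry-over class. Without that class, with p adjusted again, 17 genes were called. The counts were 412 in the blocked fit, 706 with DESeq2, 50 with the stricter filter and 1279 without batch 340. The count was 12 without alone replicate 2, 30 without alone replicate 1, 58 without BMS493 replicate 2, 66 without BMS493 replicate 1 and 243 without alone replicate 3.

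ATRA and BMS493, which act on the same receptors in opposite directions, were compared at the same dose of 1 uM. Col1a1 averaged 13.8 ± 10.8 CPM with ATRA and 212.5 ± 36.4 CPM with BMS493 (n = 3 each). The comparison therefore cannot separate the compounds from a presence of PDPN+ cells in the BMS493 cultures. Cyp26a1 was 3089-fold higher with ATRA at 224 ± 148 CPM against 0.0769 ± 0.0802 CPM. Selp was 170-fold higher (adjusted p = 2.96e-06, edgeR, n = 3), P2rx1 281-fold, Rarb 47.7-fold (adjusted p = 4.68e-05), Gata6 15.2-fold (adjusted p = 0.00112), Ccl24 353-fold and Ubash3a 314-fold higher. On the BMS493 side B3gat2 (305-fold, with 124 ± 213 CPM, an adjusted p = 0.0502 in the blocked fit and 0.575 without BMS493 replicate 2), Sod3 (302-fold) and Cbr2 (236-fold) were higher, and Sod3 and B3gat2 are at over 4 times the macrophage level in PDPN+ cells. In the cavity macrophage programme 11 of 26 members were higher with ATRA (15 adjusted over the list alone), and in the retinoic acid response list 6 of 16 (7 adjusted over the list alone), with Dhrs3, a retinaldehyde reductase gene, 4.75-fold higher. These lists had adjusted p = 0.000874 and 0.000306 with an estimated correlation. The extracellular matrix list (9 of 16 lower, adjusted p = 0.0112 with an estimated correlation) and the fibroblast list (7 of 15 lower, adjusted p = 0.0499) went the other way. With an estimated correlation the calls of 5 lists were lost: alternative activation (3 of 12 higher, Chil3 72.2-fold, adjusted p = 0.144), mast cell (0.435), cell cycle (0.422), type I interferon response (2 of 15 lower, 0.422) and mesothelial (0.423). Timd4 averaged 98.7 ± 73.7 CPM with ATRA and 1.70 ± 1.51 CPM with BMS493 (adjusted p = 0.0509, and 0.00301 in the blocked fit). Icam2, Arg1, Tgfb2 and Adgre1 were not called. Of 712 called genes 396 were higher with ATRA and 316 lower. Of the 712, 188 lay over 4 times higher in PDPN+ cells alone than in macrophages alone, with 32 of these higher with ATRA and the others lower, and stromal transcripts in the BMS493 libraries bear on them. The count of 712 stands against 1459 in the blocked fit, 1612 with DESeq2, 2231 without batch 340 and 334 in a fit of these 6 libraries alone. The count was 274 without ATRA replicate 2, 295 without BMS493 replicate 2, 345 without BMS493 replicate 1, 436 without ATRA replicate 1 and 1195 without ATRA replicate 3.

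Between transwell culture and ATRA, edgeR called 0 genes in macrophages, with 1042 at an unadjusted p under 0.05 and 95 called by DESeq2. Levels in transwell macrophages relative to ATRA were a log2 difference of -1.06 for Gata6 (SE 0.485), -0.68 for Rarb (SE 0.416) and 0.23 for Icam2 (SE 0.480). Cyp26a1 averaged 1.86 ± 2.82 CPM against 224 ± 148 CPM (adjusted p = 0.152) and Nrip1 87.1 ± 13.6 CPM against 249 ± 74.5 CPM (adjusted p = 0.136). The retinoic acid response list was lower in transwell culture (0 of 16 called, 2 adjusted over the list alone, camera adjusted p = 0.000908, adjusted p = 0.0494 with an estimated correlation). Camera also called cell cycle, immediate early and hypoxia and glycolysis higher, with 0 members called in edgeR and an adjusted p = 0.745 with an estimated correlation for each, and the inflammatory cytokine list only in the blocked fit (0.044). Tgfb2, Timd4, Arg1 and Adgre1 were not called. Without ATRA replicate 3 the count was 8, without transwell replicate 1 it was 1, and without batch 340 it was 77.

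Rarb stands in the cavity list and in the retinoic acid response list. The called genes of several comparisons overlapped. Of 50 genes higher with ATRA, 32 were also higher in co-culture (76 in the blocked fit), where independent lists would share 0.315. Simulated unchanged groups against the same controls shared 0 here and in the next overlap. No gene differs in them, so almost none is called and this 0 decides nothing. Between ATRA and co-culture the covariance of the fold changes was 0.706 against a simulated 0.278, while their correlation was 0.556 against a simulated 0.497. The simulation held no batch differences, so these contrasts are no full measure of agreement. Of the 50, 34 were among the 1510 genes lower after culture alone (4.25 for independent lists), where the correlation of the fold changes was -0.356, weaker than a simulated -0.505. These pairs share the 3 libraries of macrophages alone, which cannot be split, so part of the excess may come from them. Without a shared library, 37 of the 50 ATRA genes were among the 129 lower with BMS493 against co-culture (0.363 for independent lists, covariance -0.318 against a simulated 0.00377), and 78 of those 129 were among the genes lower after culture alone (11 for independent lists).

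In PDPN+ cells edgeR called 0 genes between co-culture and culture alone, with 1796 genes at an unadjusted p under 0.05 and 346 called by DESeq2 (281 higher and 65 lower). Dhrs3 averaged 170 ± 82.9 CPM in co-culture and 94.5 ± 8.76 CPM alone. Rarb averaged 24.9 ± 3.04 CPM against 14.8 ± 8.36 CPM (adjusted p = 0.713), Col1a1 9784 ± 4621 CPM against 3261 ± 2363 CPM (adjusted p = 0.525) and Aldh1a2 303 ± 118 CPM against 235 ± 47.5 CPM (adjusted p = 0.694). Pdpn (adjusted p = 0.702), Wt1 (0.782), Aldh1a1 (0.593), Msln (0.663) and the macrophage growth factor gene Csf1 (0.595) were not called. Pan-macrophage genes had 0 of 16 called over all genes and 14 higher when adjusted over the list alone, with Itgam at 57.7 ± 0.997 CPM (adjusted p = 0.0524) and Lyz2 at 1815 ± 387 CPM (adjusted p = 0.0941). That list had camera adjusted p = 3.28e-26 and adjusted p = 0.0623 with an estimated correlation. Hypoxia and glycolysis had 13 of 17 higher and 1 lower when adjusted over the list alone (camera adjusted p = 2.15e-08, adjusted p = 0.294 with an estimated correlation). Camera also called the cavity list (9 of 26 higher adjusted over the list alone, adjusted p = 0.149 with an estimated correlation), extracellular matrix and contractile (0.295), alternative activation (0.114), unfolded protein (0.294) and B cell (0.294) higher, and the type I interferon list lower only in the blocked fit (camera adjusted p = 0.0103). The mesothelial list was lower by camera (adjusted p = 0.000148) with 0 of 12 called, also when adjusted over the list alone, and adjusted p = 0.372 with an estimated correlation. Its members Upk3b averaged 135 against 864 CPM, Upk1b 159 against 727 CPM and Krt7 5.34 against 36.1 CPM. Wt1 changed less, at 44.7 against 57.9 CPM, and Krt19 was higher, at 9.71 against 5.07 CPM. The count stayed 0 without the libraries named next, and was 34 in a fit of these 6 libraries alone and 31 without the low count filter. PDPN+ alone replicate 3 and transwell replicate 1 stood apart with 3.35% and 3.0% of counts in mitochondrial genes.

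Transwell culture gave 0 calls in PDPN+ cells against culture alone in edgeR, with 426 genes at an unadjusted p under 0.05 and 13 called by DESeq2. Pdpn, Wt1, Aldh1a1, Aldh1a2, Rarb, Msln, Csf1 and Col1a1 each had an adjusted p of 1, with Rarb at 22.3 ± 10.4 CPM against 14.8 ± 8.36 CPM. The pan-macrophage list was higher (camera adjusted p = 2.54e-09) and the mesothelial list lower (camera adjusted p = 0.00397), as were hypoxia and glycolysis and the cavity list (higher), each with 0 members called and an adjusted p = 0.52 with an estimated correlation. Pan-macrophage genes summed to 710.7 CPM in transwell replicate 1, which stands apart, and to 113.5 and 131 CPM in transwell replicates 2 and 3, against 90.15 to 152.4 CPM alone. The inflammatory cytokine list passed only in the blocked fit (camera adjusted p = 0.0277). Between co-culture and transwell culture 1 gene was called, the leukocyte surface gene Cd84 (15.3-fold, 13.7 ± 2.02 CPM against 0.852 ± 0.205 CPM, adjusted p = 0.0131, and 0.0858 in the blocked fit), which is of the possible carry-over class. There 966 genes had an unadjusted p under 0.05 and DESeq2 called 137. Pdpn, Wt1, Aldh1a1, Aldh1a2, Rarb, Msln, Csf1 and Col1a1 were not called there. The pan-macrophage list had 0 of 16 called (6 adjusted over the list alone, adjusted p = 0.0926 with an estimated correlation). A further 9 lists passed camera with 0 members called, and with an estimated correlation their adjusted p ran from 0.263 to 0.7. The count was 0 without co-culture replicate 1 or 2 or transwell replicate 2 or 3, and 5 without transwell replicate 1.

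With 1 uM BMS493, PDPN+ cells had less Dhrs3, which encodes a retinaldehyde reductase that retinoic acid induces (chromosome 4, 144892827 to 144928209), than PDPN+ cells from co-culture. It fell 28.2-fold from 170 ± 82.9 to 6.08 ± 2.94 CPM (log2 fold change -4.82, SE 0.536, adjusted p = 0.0297, edgeR, n = 3). Resf1 fell 4.52-fold to 22.9 ± 0.118 CPM, and the predicted gene Gm42503 was the remaining call. Rarb averaged 0.249 ± 0.344 CPM against 24.9 ± 3.04 CPM with an adjusted p = 0.12, and Tgm2 34.8 ± 27.5 CPM against 220 ± 109 CPM with an adjusted p = 0.434. In the retinoic acid response list 1 of 18 fell (6 adjusted over the list alone), and the list fell with camera adjusted p = 3.69e-20 and adjusted p = 0.00307 with an estimated correlation. The cavity list (0 of 26, 4 lower adjusted over the list alone, adjusted p = 0.0984 with an estimated correlation), alternative activation (0 of 6, adjusted p = 0.0984) and the interferon list (0 of 15, adjusted p = 0.663) were lower by camera only. Pdpn, Wt1, Aldh1a1, Aldh1a2, Msln, Csf1 and Col1a1 each had an adjusted p of 1. The blocked fit called 0 of these genes (Dhrs3 adjusted p = 0.0854), with 584 genes at an unadjusted p under 0.05 in the edgeR fit and 111 calls by DESeq2. The count was 0 without replicate 1 or 2 of either group, 8 without co-culture replicate 3 and 18 without BMS493 replicate 3.

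Against PDPN+ cells alone, Dhrs3 was 15.8-fold lower with BMS493 (adjusted p = 0.0275, edgeR, n = 3) and Rarb 56.1-fold lower (adjusted p = 0.049, and 0.0501 in the blocked fit). This comparison cannot separate BMS493 from a presence of macrophages in the culture. Kng2 (45.8-fold, adjusted p = 0.0548 in the blocked fit) and Etfbkmt (10.3-fold) were lower too, and Ndufa4l2, a mitochondrial gene induced by hypoxia, was 40.4-fold higher at 26.7 ± 7.80 CPM. Macrophage genes rose: Itgam 94.0-fold, Cybb 80.4-fold and Adgre1 42.9-fold (each 0.0501 in the blocked fit), and Lyz2 47.3-fold to 2364 ± 991 CPM. The pan-macrophage list had 3 of 16 higher (14 adjusted over the list alone, camera adjusted p = 9.02e-24, adjusted p = 0.085 with an estimated correlation). In the retinoic acid response list 2 of 18 fell (5 adjusted over the list alone, camera adjusted p = 0.000162, adjusted p = 0.205 with an estimated correlation). Hypoxia and glycolysis (12 of 17 higher and 1 lower adjusted over the list alone, adjusted p = 0.368 with an estimated correlation), extracellular matrix and contractile (0.368), unfolded protein (0.211) and B cell (0.22) were higher by camera only, and type I interferon response (0.368) and cholesterol synthesis (0.751) lower. The mesothelial list was lower by camera (adjusted p = 6.86e-06) with 0 of 12 called and adjusted p = 0.368 with an estimated correlation, and Wt1 (adjusted p = 0.42), Msln (0.589), Aldh1a1 (0.59), Aldh1a2 (0.889), Csf1 (0.515), Col1a1 (0.511) and Pdpn (0.942) were not called. Of 46 called genes 31 were higher and 15 lower. The blocked fit called 20 higher and 21 lower, and 21 genes were called in both fits. The count of 46 stands against 693 with DESeq2, 1 without carry-over genes (30 of the 46 are of that class, and p was adjusted again over the genes left), 5 without libraries from under 10000 cells, which leaves 2 BMS493 libraries, and 42 without the libraries that stand apart, of which 13 are among the 46. The count was 0 without alone replicate 2, alone replicate 3 or BMS493 replicate 2, 6 without alone replicate 1, 22 without BMS493 replicate 3 and 27 without BMS493 replicate 1.

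**Figure D4:**
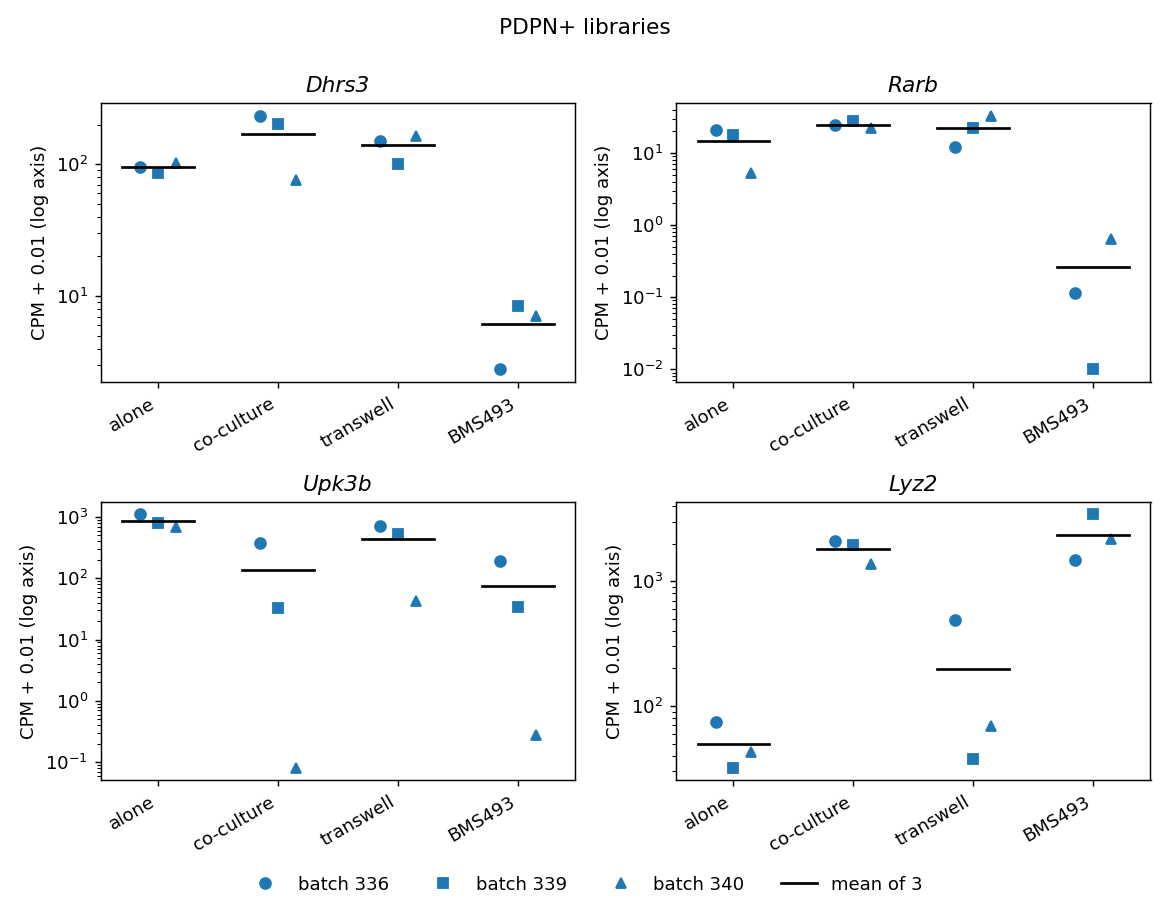
Levels of Dhrs3, Rarb, Upk3b and Lyz2 in the 4 PDPN+ groups, as CPM plus 0.01 on a log axis, with a point per library, the shape giving the batch and the bar the mean of 3. Mean Dhrs3 was 94.5 CPM alone, 170 in co-culture, 139 in transwell culture and 6.08 with BMS493.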

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

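The joint fit of both cell types behind the following values was added after the data were seen. It had group as its only factor, with no batch block, although same-numbered libraries share a batch. No library was left out of it in turn, so the stability of these differences was not tested. In the macrophage fit without alone replicate 2, Gata6 (adjusted p = 0.0679, edgeR), Rarb (0.058) and Cyp26a1 (0.124) were not called for co-culture over alone. Gata6 and a few retinoic acid response genes moved differently in the 2 cell types under the same culture contrast. Across 57 tests (19 genes in 3 contrasts), 10 differences passed an adjusted p under 0.05 in edgeR (n = 3 per group), of which 9 are given here, each value being the macrophage minus the PDPN+ log2 fold change. Dhrs3 differed by 3.4 for BMS493 over co-culture (adjusted p = 0.000613), falling by 1.42 in macrophages and by 4.82 in PDPN+ cells. Gata6 differed by 4.56 for co-culture over alone (adjusted p = 0.00152), by 3.265 for transwell over alone (adjusted p = 0.014) and by -3.42 for BMS493 over co-culture (adjusted p = 0.0113). In PDPN+ cells its fitted log2 fold changes were -1.237 (154.9 ± 38.3 to 65.0 ± 43.7 CPM), -0.532 and -0.001. These enter the differences, but edgeR called 0 genes in PDPN+ cells for co-culture or transwell over alone. A change of Gata6 in PDPN+ cells is therefore not settled. Mesothelial genes there were lower as a list after co-culture by camera (Upk3b 864 to 135 CPM). That call was lost with an estimated correlation, and 0 members were called. Rarb differed by 2.881 for co-culture over alone (adjusted p = 0.0295), with 0.774 in PDPN+ cells, and Tgm2 by 2.724 for transwell over alone (adjusted p = 0.0185), with -0.713 in PDPN+ cells.

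Cyp26a1 differed by 13.23 for co-culture over alone (adjusted p = 0.00273), by 10.78 for transwell over alone (adjusted p = 0.0158) and by -7.679 for BMS493 over co-culture (adjusted p = 0.0162), with -1.519, -1.639 and 0.452 in PDPN+ cells. The first pair of these rest on 0 counts in macrophages cultured alone, so their size is no bound.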

How the results depend on the processing

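The tests without batch 340 and without the PDPN+ libraries that stand apart, and the overlaps of calls without a shared library, were chosen after the data were seen. Selp kept its call for ATRA, co-culture and transwell against alone and for BMS493 against co-culture in every omission of 1 of the 6 compared libraries. Rarb and Gata6 did so for ATRA against alone and for alone against ex vivo. Over the other settings the highest adjusted p was 0.188 for Rarb and 0.0808 for Gata6 with ATRA, and 0.135 for Selp in transwell culture. Those calls were therefore not kept in every setting. Over 739 gene results, 8201 of 9543 alternative values kept their direction and their side of the threshold. Of the others, 933 lost a call, 291 gained a call and 117 changed sign without a call in either setting. The 739 include genes not called in the main fit, which keep their side by staying uncalled. The 8201 are therefore no measure of how stable the calls are. One value changed sign with a call: Arg1 for macrophages alone against ex vivo, at 0.88 on the log2 scale, was -3.233 without batch 340 (adjusted p = 0.019), and its adjusted p over the other alternatives ran from 0.0854 to 0.865. The counts below follow the order of the report, and where no cause is given the cause was not tested. With the replicate block the macrophage counts were 143 for ATRA, 429 for co-culture, 23 for transwell, 33 for contact, 320 for BMS493 against co-culture, 412 for BMS493 against alone and 1459 for ATRA against BMS493, and in PDPN+ cells 0 for contact, 0 for BMS493 against co-culture and 41 for BMS493 against alone (21 of the 46). The genes shared by ATRA and co-culture numbered 76. Among the 739 gene results the block ended 9 calls and added 35, and beside the lists given in the report it changed no other call of a list. DESeq2 gave 331, 703, 262, 152, 444, 706, 95 (transwell against ATRA) and 1612 in macrophages and 346, 13, 137, 111 and 693 in PDPN+ cells. Fits of the 6 compared libraries alone gave 1952 for culture alone, 3, 1, 0, 0, 75 and 334 for ATRA, co-culture, transwell, contact, BMS493 against co-culture and ATRA against BMS493, and 34, 4, 0 and 15 in PDPN+ cells for co-culture, contact, BMS493 against co-culture and BMS493 against alone. Without batch 340 the counts were 106, 930, 323, 314, 1279, 77 and 2231 for ATRA, co-culture, transwell, BMS493 against co-culture, BMS493 against alone, transwell against ATRA and ATRA against BMS493. RLE scaling gave 3 for transwell macrophages. With no low count filter the counts were 3 for transwell, 15 for contact and 2 for transwell against ATRA in macrophages, and 31, 3, 6 and 78 in PDPN+ cells for co-culture, contact, BMS493 against co-culture and BMS493 against alone. The stricter filter, with fewer genes tested, gave 9, 2 and 50 for transwell, contact and BMS493 against alone in macrophages, and 1, 2 and 9 in PDPN+ cells for co-culture, contact and BMS493 against alone. Without carry-over genes, with p adjusted again over the genes left, 48, 1, 0 and 17 were called for co-culture, transwell, contact and BMS493 against alone in macrophages, and 0 and 1 for contact and BMS493 against alone in PDPN+ cells. Genes removed by construction make up 62 of 124, 1 of 5, 7 of 7 and 90 of 131 calls in macrophages and 1 of 1 and 30 of 46 in PDPN+ cells, and the remaining losses come from the new adjustment. Without libraries from under 10000 cells the PDPN+ counts were 0 for co-culture, 0 for contact, 0 for BMS493 against co-culture and 5 for BMS493 against alone. This leaves 1 co-culture library, so the first 3 counts say nothing about stability, and 2 BMS493 libraries. Without the libraries that stand apart the contact count was 6. Of 112 list calls 28 held with an estimated correlation and 48 were made by fry. Leaving out 1 library gave 2107 to 2984 genes for culture alone, 17 to 73 for ATRA, 5 to 268 for co-culture, 1 to 43 for transwell, 0 to 14 for contact, 43 to 138 for BMS493 against co-culture, 12 to 243 for BMS493 against alone, 0 to 8 for transwell against ATRA and 274 to 1195 for ATRA against BMS493. In PDPN+ cells it gave 0 to 0 for co-culture and for transwell, 0 to 5 for contact, 0 to 18 for BMS493 against co-culture and 0 to 27 for BMS493 against alone. Of the called genes named or in the lists, 82 of 129 for culture alone, 7 of 21 for ATRA, 2 of 37 for co-culture, 1 of 5 for transwell, 0 of 5 for contact, 8 of 34 for BMS493 against co-culture, 4 of 26 for BMS493 against alone and 27 of 55 for ATRA against BMS493 kept their call in every omission, and in PDPN+ cells 0 of 1 for contact, 0 of 2 for BMS493 against co-culture and 0 of 9 for BMS493 against alone did. Depth limits the genes at 0 to 3 counts, among them Cyp26b1 in co-culture (1 count), transwell (0) and BMS493 (0) macrophages.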

Other observations

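The tests on the PDPN+ libraries that stand apart, on stromal genes in macrophages, on Gata6, Rarb and Cyp26a1, and on batch 340 were chosen after the results were seen. In the 5 cultured macrophage libraries of batch 340 inflammatory genes were higher than in the 10 others, with group in the fit. The chemokine gene Cxcl3 averaged 1782 against 10.9 CPM, the activin gene Inhba 522 against 3.75 CPM, Il1b 241 against 2.90 CPM and Mmp12 19660 against 1745 CPM. Apoe, a lipid carrier gene, averaged 576 against 29330 CPM, Gas6 29.2 against 758 CPM and Cd209a 4.75 against 229 CPM. Arg1 was higher (log2 difference 2.59, adjusted p = 0.00943, edgeR), while Adgre1 (adjusted p = 0.922) and Gata6 (adjusted p = 0.522) were not called. In the inflammatory cytokine list 14 of 18 genes were higher and 1 lower (camera adjusted p = 5.32e-11, adjusted p = 0.00425 with an estimated correlation), and in hypoxia and glycolysis 10 of 17 were higher (1.43e-05, adjusted p = 0.348 with an estimated correlation). Pan-macrophage genes were lower in 8 of 16 cases and higher in 1 (0.000715, adjusted p = 0.316 with an estimated correlation). Mast cell genes were lower in 5 of 5 cases (camera adjusted p = 0.0107, adjusted p = 0.551 with an estimated correlation). The labels do not say what differed between the batches.

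PDPN+ alone replicate 3 and transwell replicate 1 stood apart from the other 10 PDPN+ libraries in mitochondrial counts (3.35% and 3.0%, against at most 1.26%). Macrophage RNA is argued against, since pan-macrophage genes summed to 100 CPM in the former and 710.7 CPM in the latter (113.5 and 131 CPM in transwell replicates 2 and 3), against 1800 CPM in the lowest co-culture library. Some macrophage RNA in transwell replicate 1 is not excluded. Few sorted cells are argued against as well, since 25000 cells lay behind each, with a median of 25000. Loss of reads from long transcripts may contribute, since the correlation across genes of deviation with exon length was -0.332 or lower in both and -0.119 at the lowest in the others. No biological explanation was tested.

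Stromal and matrix genes higher in co-culture macrophages may come from PDPN+ RNA in these libraries. The 62 called genes of the possible carry-over class rose by a median of 2.81% of the PDPN+ level, beside 2.13% for the fibroblast list. That class also holds Gata6, Rarb and Cyp26a1 and shares members with the fibroblast list, so its median is not that of stromal genes alone. For Gata6, Rarb and Cyp26a1 the fibroblast list ratio would supply at most 2.89% of the increase, which argues against this source for them. A response of these genes to the stromal cells stays open as a hypothesis. For the called genes at no more than 4 times the macrophage level in PDPN+ cells it would supply a median of 0.717%. That test decides nothing, since the choice of these genes alone holds the share to a median of at most 2.59%, so the source of their increase stays open. The share was not worked out for Aldh1a2, which is of the possible carry-over class.

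Mesothelial genes were lower as a list in co-culture PDPN+ cells by camera (adjusted p = 0.000148, adjusted p = 0.372 with an estimated correlation). Upk3b stood at 135 against 864 CPM, Upk1b at 159 against 727 CPM, Lrrn4 at 62.0 against 422 CPM and Gpm6a at 61.5 against 391 CPM. These genes were chosen after their values were seen. Among other members, Wt1 (44.7 against 57.9 CPM) and Bnc1 (96.9 against 160 CPM) changed less, and Krt19 was higher (9.71 against 5.07 CPM). The list summed to 602 ± 757 CPM in co-culture and 2744 ± 778 CPM alone. Replicates 2 and 3 of the co-culture came from 3730 and 2148 cells, and in replicate 1, with 25000 cells in both libraries, the median log2 ratio was -1.05, with an upper quartile of -0.0607, beside -3.27 in replicate 2 and -7.24 in replicate 3. The median of replicate 1 passed the bound set beforehand, but the members' spread reached it and 1 pair of libraries excludes nothing, so few sorted cells cannot be told apart from the other explanations. Distortion of alone replicate 3 is argued against, since the median fitted change was -2.09 without it and -2.19 with it. A smaller share of mesothelial cells may be the source and stays open, as the interquartile range over 9 members was 1.5.

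Other splits of the 6 libraries of each comparison were counted, and 10 splits are too few for a share under 0.05. The number of splits with as many genes, the real one included, was 1 for culture alone (3164 genes, highest other 8), 2 for ATRA (58, highest other 808), 1 for co-culture (124, 0), 1 for transwell (5, 0), 1 for contact (7, 0), 1 for BMS493 against co-culture (129 lower and 22 higher, highest other 1), 1 for BMS493 against alone (131, 0), 10 for transwell against ATRA (0, 1) and 1 for ATRA against BMS493 (712, 0). In PDPN+ cells it was 10 for co-culture (0, 0), 10 for transwell (0, 0), 2 for contact (1, 1), 1 for BMS493 against co-culture (3, 0) and 1 for BMS493 against alone (46, 1). The ATRA split that called 808 genes points to a structure of the samples. It put both batch 340 libraries on the same side, but 3 other splits that did so called 0 genes, so batch 340 by itself does not account for it. The blocked fit called 143 genes. Among the 4 splits that part all pairs, as the real one does, the highest other was 0 in each comparison.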
